A study of Mus musculus with 6 samples.

How the data were processed

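Polyadenylated RNA of 6 libraries of cultured mouse stromal cells was compared, 3 treated with PBS and 3 with 10 nM irisin/HSP90α for 3 days. Per the labels' protocols, cells were lysed in a 96-well plate in TCL buffer with 2-mercaptoethanol, and a part of each lysate went into the ultra-low-input RNA-seq procedure of the Immunological Genome Project. Per the submitters' processing notes, STAR 2.7.3a, featureCounts and the mouse build mm10 were used. The annotation release, strand setting, multi-mapping rule and read filters are not given in the sources used here. The authors deposited whole-number counts per gene symbol for all 6 libraries in one table of 55011 genes, with no normalization. Columns were matched to samples by the library names in the labels, and groups and replicate numbers came from the sample titles.

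From these deposited counts, edgeR 4.0.16 in R 4.3.3 computed normalization factors by TMM, kept genes with filterByExpr at a count minimum of 10 (12296 of 31436 genes with any count), and ran the robust quasi-likelihood test of irisin against PBS with no other term. P-values were adjusted by the Benjamini-Hochberg method, with 0.05 as threshold. TMM factors were 1.02 to 1.03 in PBS and 0.969 to 0.981 in irisin, and the common biological coefficient of variation was 0.121. Levels in CPM divide counts by the TMM-scaled sum of the tested genes, for single genes and for summed marker lists alike. Total counts per library lay between 5271309 and 6745799, so a level of 1 CPM stood on about 5 to 7 counts.

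Before the data were examined, 42 gene lists, the alternatives and the naming rule were fixed. The lists covered stromal immune functions, the adipocyte lineage, matrix, signalling, stress and metabolic pathways, other cell types and RNA quality. Each list was counted by members past the threshold over all genes and when adjusted over the list alone. The 37 lists with at least 5 tested genes were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 37 lists, again with an estimated correlation, and with fry. Summed marker levels were compared by exact two-sided permutation tests, for which 3 against 3 gives p = 0.1 at the least.

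The named genes were 18 fixed ones, the 10 largest rises and the 10 largest falls among called genes with a mean of at least 10 CPM and groups that did not overlap, and up to 4 members of lowest p in each list. Predicted genes and pseudogenes were left out of the largest changes. Where a list had 5 or fewer members called in a direction, they were named as well, and these, with any others marked so, were chosen after their values were seen. Some members of the lists that passed are not reported here by name.

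Alternatives were RLE and upper quartile factors, total counts alone, DESeq2 1.42.0, limma-voom with sample quality weights, no robust dispersion, no low-count filter, a count minimum of 50, and mitochondrial and ribosomal protein genes left out. The replicate number as a block, each library left out in turn, an adjusted p of 0.10 and a test against a 1.5-fold change were run as well. Leaving out PBS replicate 3 and irisin replicate 1 together was added after the data were seen.

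The test steps were first tested on simulated data for irisin against PBS, with 200 of 12119 genes changed. edgeR recovered 44% of those changed 1.5-fold, 90% at 2-fold, 98% at 4-fold and 100% at 8-fold, and 12 of its 178 calls were unchanged genes. For lists of 25 members, camera called 20 of 20 that were shifted 1.5-fold and 0 of 20 that were not. The simulated genes were drawn independently, so this does not test camera on lists whose members correlate, such as the interferon list (estimated correlation 0.79). Chi-square per degree of freedom between libraries of a group ran from 2.74 (irisin replicates 2 and 3) to 14.8 (PBS replicates 2 and 3), and from 25.8 to 35.4 between groups, so no library repeated another. Positions came from GENCODE M21 by symbol, which matched 53009 of the 55011 symbols (96.4%). The label irisin/HSP90α was read as both proteins together, and if HSP90α was also in the PBS wells the contrast is of irisin alone.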

Results

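Messenger RNA was counted in 6 libraries of cultured mesenchymal stromal cells, the connective-tissue cells of fat that include the precursors of adipocytes. The cells came from mouse visceral fat, which the design text calls eWAT, a usual abbreviation for epididymal white adipose tissue. They were negative for the EGFP reporter of Il33, the gene of an alarmin cytokine that acts through the receptor ST2 (gene Il1rl1). The cells were kept for 3 days with phosphate-buffered saline (PBS, n = 3) or with 10 nM irisin/HSP90α (n = 3, called irisin here). The sample titles name irisin alone and the treatment labels irisin/HSP90α, which is read here as both proteins together. Whether the PBS wells held HSP90α is not stated. Irisin is a hormone released from the muscle protein Fndc5, and HSP90α is a chaperone that also occurs outside cells. Total counts were 6745799, 6199889 and 5271309 for PBS replicates 1, 2 and 3, and 6396422, 5360724 and 6588363 for irisin replicates 1, 2 and 3. Between 19816 and 22083 genes had a count in a library. The design asks whether irisin/HSP90α moves these cells from adipocyte precursors towards immunomodulatory stromal cells, and irisin against PBS is its comparison. Levels below are CPM, read counts scaled to library size, given as mean ± SD over 3 libraries per group, and pairs of levels run from PBS to irisin. Log2 fold changes (LFC) are irisin against PBS, ± standard error. Adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested.

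After 3 days with irisin, genes of the acute-phase and NF-κB response and several chemokines were higher. In the adipocyte differentiation list 25 of 31 members were lower (camera adjusted p = 3.87e-41, and adjusted p = 0.0501 with an estimated correlation). Saa3, a serum amyloid A protein of the acute phase, rose 88.8-fold, from 105 ± 13 to 9349 ± 602 CPM (LFC 6.47 ± 0.10, adjusted p = 8.89e-12). Il33 itself rose 12.4-fold, from 8.40 ± 1.18 to 104 ± 20.0 CPM (LFC 3.64 ± 0.17, adjusted p = 3.91e-08), in cells that had been negative for its reporter. Adipoq, which encodes the adipocyte hormone adiponectin, fell from 40.9 ± 10.4 to 9.84 ± 1.11 CPM (LFC -2.06 ± 0.20, adjusted p = 1.44e-05). Aqp7, the glycerol channel of adipocytes, fell from 23.6 ± 0.787 to 3.19 ± 0.966 CPM and was 7.44-fold lower (LFC -2.90 ± 0.23, adjusted p = 2.02e-06). Of 12296 genes tested, 912 (7.42%) passed adjusted p 0.05, of which 516 were higher and 396 lower with irisin. Among them, 208 of the higher and 158 of the lower genes changed at least 2-fold. With libraries scaled by total counts alone, 422 genes were higher and 602 lower, so that 41.2% of the calls were upward against 56.6%. That scaling moved the median log2 fold change of all genes tested from -0.01 to -0.09. In 911 of the 912 called genes the 3 irisin values lay wholly above or below the 3 PBS values, against 23.6% of all genes tested and 10% by chance. The call count fell to 605 without PBS replicate 1, to 589 without irisin replicate 2 and to 596 without irisin replicate 3. The lower genes numbered 250, 238 and 260 in these fits, and the higher genes 336 without irisin replicate 3. The first principal component (47.1% of variance) separated irisin from PBS, and the next (23.9%) set PBS replicate 3 and irisin replicate 1 apart from the other 4 libraries. With both of these left out, an alternative chosen after the data were seen, 1680 genes passed (892 higher, 788 lower), and 869 of the 912 were among them. The remaining libraries were the closest pair of each group (chi-square per degree of freedom 4.15 in PBS and 2.74 in irisin), so this choice favours more calls. Its counts, here and for the lists below, are therefore no independent support. The labels do not say that replicates were separate cultures or animals, so the p-values measure the spread between these samples, which may be technical.

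**Figure D1:**
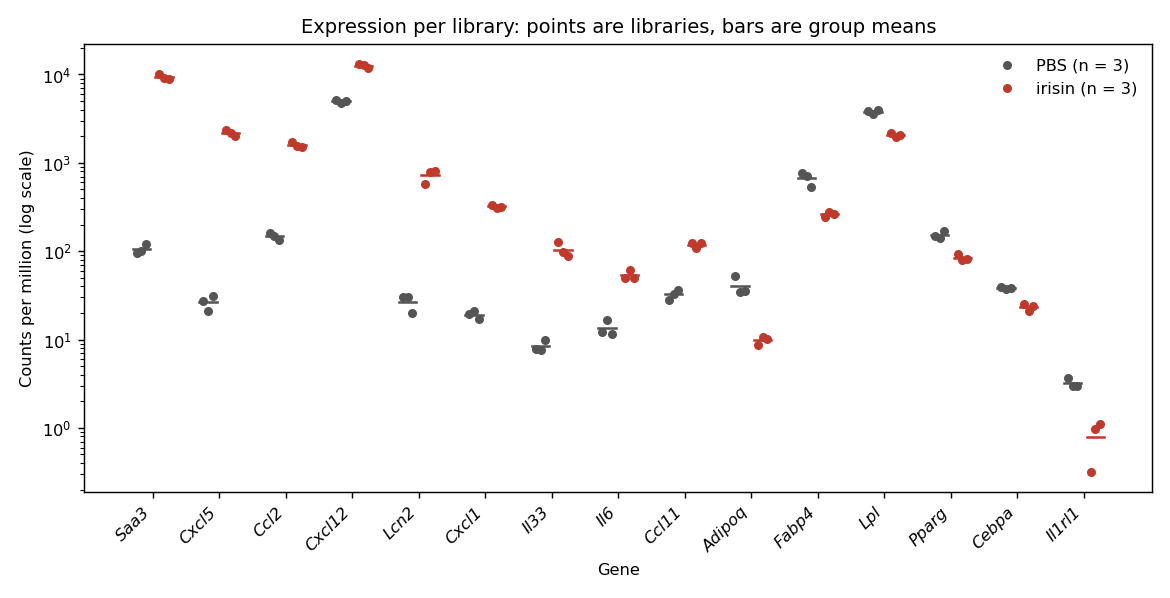
CPM on a log axis (vertical) for 15 genes (horizontal), with one point per library, PBS in grey (n = 3) and irisin in red (n = 3), and bars at the group means. All 3 irisin points lie above all 3 PBS points for Saa3 (means 105 and 9349 CPM) and Il33 (8.40 and 103.9 CPM), and below them for Adipoq (40.9 and 9.84 CPM) and Il1rl1 (3.19 and 0.795 CPM).

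Among called genes with a mean of at least 10 CPM, the largest rises were, after Saa3, Cxcl5 (82.3-fold, 26.4 ± 4.88 to 2167 ± 158 CPM), a chemokine that attracts neutrophils, and Lcn2 (27.0-fold, 26.8 ± 5.97 to 727 ± 126 CPM), a secreted protein that binds bacterial iron carriers. Cxcl1, another neutrophil chemokine, rose 16.7-fold (LFC 4.06 ± 0.10, adjusted p = 1.20e-10), and Ccl2, which attracts monocytes, rose 10.8-fold from 148 ± 12.8 to 1592 ± 124 CPM (adjusted p = 3.93e-10). Serpinb2, an inhibitor of plasminogen activators, rose 16.2-fold (LFC 4.01 ± 0.15, adjusted p = 5.58e-09), and Serpina3i, a serine protease inhibitor, 9.25-fold (LFC 3.21 ± 0.23, adjusted p = 5.47e-07). Ifitm1, an interferon-induced membrane protein, rose 14.1-fold (LFC 3.81 ± 0.23, adjusted p = 1.64e-07), and Ndufa4l2, a mitochondrial protein induced by low oxygen, 9.99-fold (LFC 3.32 ± 0.23, adjusted p = 5.28e-07). With Il33 and Ccl2 these are the 10 largest rises under the naming rule. The 10 largest falls were led by Aqp7, by Cilp, a cartilage matrix protein (LFC -2.84 ± 0.13, adjusted p = 8.30e-08), by Sult1e1, an oestrogen sulfotransferase (LFC -2.70 ± 0.18, adjusted p = 4.54e-07), and by Adrb3, the β3-adrenergic receptor of adipocytes (LFC -2.61 ± 0.35, adjusted p = 0.000491). Slc40a1, the iron exporter ferroportin (LFC -2.26 ± 0.20, adjusted p = 6.20e-06), Reep6, an endoplasmic reticulum protein (LFC -2.25 ± 0.19, adjusted p = 6.29e-06), and Adh1, an alcohol dehydrogenase that also oxidises retinol (LFC -2.19 ± 0.12, adjusted p = 1.39e-07), were also among them. So were Cfd, which encodes adipsin (LFC -2.37 ± 0.39, adjusted p = 0.0182), Car3, a carbonic anhydrase abundant in fat (LFC -2.26 ± 0.27, adjusted p = 0.00626), and Arc, an immediate-early gene (LFC -2.44 ± 0.55, adjusted p = 0.0389). Cfd lost its call without PBS replicate 3 or irisin replicate 2 (adjusted p 0.0857 to 0.110). Its call was also lost with limma-voom (adjusted p = 0.0716), with no low-count filter (0.0891) and with PBS replicate 3 and irisin replicate 1 both left out (0.231). The call of Car3 was lost without PBS replicate 3 (adjusted p = 0.0553). It was also lost with no low-count filter (0.0646), with the replicate block (0.0667) and with the 2 libraries left out (0.144). Arc was no longer called without PBS replicate 1 or 2 or irisin replicate 1, 2 or 3 (adjusted p 0.0551 to 0.147), nor with the replicate block (0.0608).

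Coordinates are those of the mouse assembly GRCm38 (mm10) in GENCODE release M21. Il33 lies on chromosome 19 from 29925114 to 29960718, and Il1rl1 on chromosome 1 from 40429570 to 40465415. Saa3 lies on chromosome 7 (46711998 to 46715700), Cxcl5 on chromosome 5 (90759360 to 90761624), Ccl2 on chromosome 11 (82035571 to 82037453), Adipoq on chromosome 16 (23146536 to 23158028) and Pparg on chromosome 6 (115360951 to 115490399). These 7 genes are annotated as protein-coding, and none shares exon bases with another annotated gene. Each count is a sum over a gene, so exons, introns and untranslated regions were not told apart. Serpinb2 shares 291 exon bases with Serpinb10 on the same strand, and Cfb shares 2246 with a predicted gene on its strand. Exons of a gene on the opposite strand overlap Adrb3 (839 bases), Icam1 (511), Itgav (634), Pdgfra (456), Ndufa4l2 (32), Adh1 (136) and Timp3 (1733), among other genes named here. The sources used here do not state whether counting used strand, so those values are uncertain to that extent. The same holds for families with similar members (Saa, Serpina3, H2-Q, Mt1 with Mt2), among which the counting could divide reads. How far it did so was not measured.

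Immunomodulatory stromal genes, a list of cytokines, chemokines and adhesion molecules, rose as a group. Of 28 members tested, 15 rose and 3 fell, with 10 not past the threshold, and 19 and 4 when adjusted over the list alone (median log2 fold change 0.89, camera adjusted p = 3.00e-55). Besides Cxcl5, Cxcl1, Ccl2 and Il33, the rises included Cxcl12, the most abundant chemokine named here, from 4971 ± 156 to 12493 ± 677 CPM (LFC 1.33 ± 0.08, adjusted p = 5.28e-07). Il6, an inflammatory cytokine, rose 3.92-fold from 13.5 ± 2.85 to 53.3 ± 6.59 CPM (adjusted p = 4.72e-06), and Ccl11, the eosinophil attractant eotaxin, rose 3.66-fold from 32.5 ± 4.25 to 119 ± 7.96 CPM (adjusted p = 4.50e-07). Icam1, an adhesion molecule for leukocytes, rose 1.81-fold (LFC 0.86 ± 0.08, adjusted p = 2.27e-05). The 3 falls, named after their values were seen, were Ptgs2, a prostaglandin synthase (LFC -1.35 ± 0.18, adjusted p = 0.000245), Tnfrsf11b, the decoy receptor osteoprotegerin (LFC -0.98 ± 0.10, adjusted p = 1.92e-05), and Tslp, an epithelial and stromal cytokine (LFC -0.75 ± 0.18, adjusted p = 0.0215). Tslp lost its call without irisin replicate 2 or 3 (adjusted p 0.103 to 0.108). The list shares 11 members with the NF-κB list, and of the remaining 17 members 7 rose and 2 fell (median 0.39, camera p = 6.54e-13, and p = 0.00151 with an estimated correlation). Immunomodulatory falls numbered 5 without both PBS replicate 3 and irisin replicate 1.

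Il1rl1, which encodes the Il33 receptor ST2, was low in both groups and fell while Il33 rose. It fell from 3.19 ± 0.377 to 0.795 ± 0.417 CPM (LFC -2.00 ± 0.48, adjusted p = 0.0129), on 16 to 25 counts per PBS library and 2 to 7 per irisin library. The call of Il1rl1 was lost without PBS replicate 1 or irisin replicate 1 (adjusted p 0.0586 to 0.0682). The integrin subunits Itgav and Itgb5, which form a reported irisin receptor, did not pass (LFC 0.24 ± 0.14, adjusted p = 0.423, and LFC -0.29 ± 0.09, adjusted p = 0.0746). Itgb5 passed as lower with total counts (adjusted p = 0.0256), with limma-voom (0.0237) and without PBS replicate 3 and irisin replicate 1 (0.00557). Hsp90aa1, the gene of HSP90α, did not pass (174 ± 19.8 to 177 ± 9.38 CPM, LFC 0.03 ± 0.10, adjusted p = 0.938), and neither did Fndc5, the gene that encodes the irisin precursor (3.83 ± 1.22 to 2.12 ± 0.556 CPM, LFC -0.88 ± 0.36, adjusted p = 0.192). Of 19 integrin and focal adhesion genes tested, 2 rose and 2 fell, and 2 and 3 when adjusted over the list alone (camera adjusted p = 0.761). They were Src (LFC 0.67 ± 0.16, adjusted p = 0.0174) and Itgb8 (LFC 1.61 ± 0.44, adjusted p = 0.0387), which were higher, and Itgb3 (LFC -1.18 ± 0.21, adjusted p = 0.00248) and Itgb1 (LFC -0.52 ± 0.13, adjusted p = 0.0308), which were lower. The rises numbered 0 without PBS replicate 2 or irisin replicate 2 and 1 without irisin replicate 1 or 3. The falls numbered 4 without PBS replicate 3, and 1 without PBS replicate 1, PBS replicate 2, irisin replicate 1 or irisin replicate 2. Src was no longer called without PBS replicate 2 or irisin replicate 2 (adjusted p 0.0632 to 0.106). Itgb8 lost its call without PBS replicate 2 or irisin replicate 1, 2 or 3 (adjusted p 0.0643 to 0.177). The call of Itgb1 was lost without PBS replicate 1 or 2 or irisin replicate 1 or 2 (adjusted p 0.1003 to 0.139). Integrin rises numbered 1 with no robust dispersion or with a count minimum of 50. The integrin falls numbered 6 without both PBS replicate 3 and irisin replicate 1.

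NF-κB target genes rose as a group. Of 34 members tested, 24 rose, 1 fell and 9 did not pass, with 26 and 1 when adjusted over the list alone (median log2 fold change 1.07, camera adjusted p = 4.31e-83). After Cxcl5, Cxcl1 and Ccl2, the member with the lowest p was Sod2, the mitochondrial superoxide dismutase (229 ± 9.92 to 749 ± 27.2 CPM, LFC 1.71 ± 0.08). The member that fell was Ptgs2. Acute-phase and innate defence genes rose in 15 of 18 members, and 1 fell, with 15 and 2 when adjusted over the list alone (median 1.60, camera adjusted p = 1.46e-78). Hp, which encodes the haemoglobin-binding haptoglobin, rose from 1964 ± 102 to 7961 ± 341 CPM (LFC 2.02 ± 0.08), Cp, the ferroxidase ceruloplasmin, from 358 ± 32 to 1289 ± 68.8 CPM (LFC 1.85 ± 0.09), and Serpina3g from 12.1 ± 1.85 to 68.3 ± 2.78 CPM (LFC 2.49 ± 0.14). The member that fell was Il1rl1, a call lost without PBS replicate 1 or irisin replicate 1 (adjusted p = 0.0682 and 0.0586). Of the 19 lists that camera called with its preset correlation, 10 up and 9 down, these 2 lists, the immunomodulatory list and the glycolysis list held with an estimated correlation. Their adjusted p-values were then 0.000605 for the NF-κB and acute-phase lists and 0.00303 for the other pair, and the other 15 lists did not hold. The unadjusted camera p of the NF-κB list rose from 1.16e-84 to 2.25e-05, though its estimated correlation (-0.0073) lay below the preset 0.01. For the complement list (-0.00695) it rose from 0.00138 to 0.0273. A call lost with an estimated correlation is therefore not by itself a sign that members correlate. NF-κB falls numbered 2 without both PBS replicate 3 and irisin replicate 1. Acute-phase falls numbered 0 with a count minimum of 50.

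Adipocyte genes fell. In the adipocyte differentiation list 25 of 31 members tested were lower and none was higher, with 27 lower when adjusted over the list alone (median log2 fold change -1.30, camera adjusted p = 3.87e-41, and adjusted p = 0.0501 with an estimated correlation). Pparg and Cebpa, the transcription factors that drive adipogenesis, fell from 153 ± 16 to 84.5 ± 7.50 CPM (LFC -0.86 ± 0.10, adjusted p = 0.000156) and from 38.3 ± 1.19 to 23.4 ± 1.93 CPM (LFC -0.70 ± 0.12, adjusted p = 0.00261). Fabp4, a fatty acid carrier of adipocytes, fell from 669 ± 121 to 262 ± 16.5 CPM (LFC -1.36 ± 0.12, adjusted p = 1.52e-05), and Lpl, the lipase that releases fatty acids from lipoproteins, from 3809 ± 191 to 2073 ± 104 CPM (LFC -0.88 ± 0.08, adjusted p = 1.72e-05). Cd36, a fatty acid transporter, fell from 166 ± 16.8 to 42.1 ± 3.03 CPM (LFC -1.97 ± 0.11, adjusted p = 1.39e-07), and the lipid droplet proteins Plin1 (LFC -1.71 ± 0.14, adjusted p = 4.81e-06) and Plin4 (LFC -1.61 ± 0.15, adjusted p = 1.17e-05) were lower as well. Of 8 mature adipocyte markers tested, 7 fell, and 8 when adjusted over the list alone (median -2.22, camera adjusted p = 1.22e-22, and adjusted p = 0.0501 with an estimated correlation). With fry, which tests a list against no change, directional adjusted p was 0.00342 for the adipocyte differentiation list and 0.00437 for these markers. Both lists share 7 members, and the other 24 adipocyte genes held 18 falls (median -0.90, camera p = 1.64e-26, and p = 0.00933 with an estimated correlation). The summed level of the mature adipocyte markers was 788 ± 226 CPM in PBS, with 1048 in PBS replicate 1, and 171 ± 32.3 CPM in irisin. The exact two-sided permutation test of that sum gave p = 0.1, the smallest that 3 against 3 allows.

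**Figure D2:**
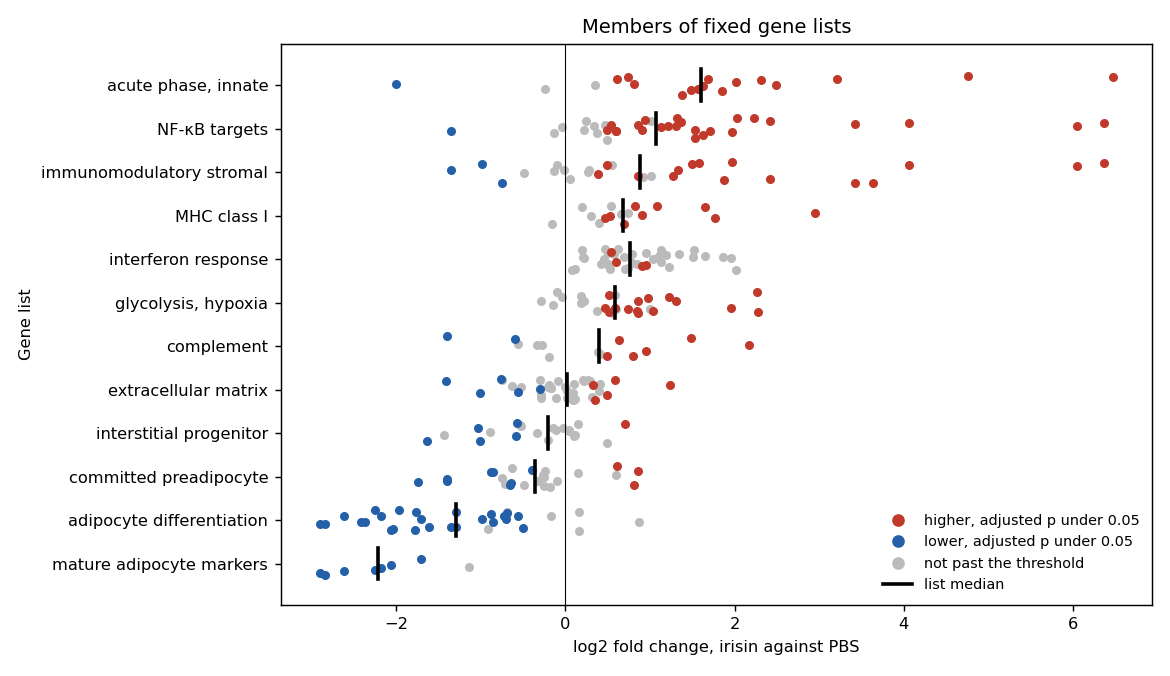
Log2 fold change, irisin against PBS (horizontal), of each tested member of 12 gene lists (vertical), with members higher at adjusted p under 0.05 in red, lower in blue and the rest in grey, and a black bar at each list's median. List medians run from -2.22 for the mature adipocyte markers to 1.60 for the acute-phase list.

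Genes of committed preadipocytes went both ways. Of 24 tested, 8 fell and 3 rose, with 12 and 3 when adjusted over the list alone (median log2 fold change -0.36, camera adjusted p = 1.59e-06, and adjusted p = 0.125 with an estimated correlation). Without PBS replicate 3 the falls numbered 13. Gdf10, a secreted TGF-β family member, fell from 127 ± 20.4 to 37.9 ± 3.03 CPM (LFC -1.74 ± 0.13), and Cd34, a surface protein of progenitor cells, from 103 ± 5.42 to 38.9 ± 7.17 CPM (LFC -1.40 ± 0.13). Gas6, a ligand of the TAM receptors, fell from 904 ± 53.3 to 499 ± 5.53 CPM (LFC -0.86 ± 0.08), and Lpl is also on this list. The rises were Pdgfra, a receptor that marks fat stromal cells (1161 ± 36.3 to 1765 ± 150.2 CPM, LFC 0.60 ± 0.09, adjusted p = 0.000620), Icam1 and Steap4, a metalloreductase (608 ± 23.7 to 1067 ± 40.2 CPM, LFC 0.81 ± 0.08, adjusted p = 2.05e-05). Preadipocyte falls numbered 15 without both PBS replicate 3 and irisin replicate 1.

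In the interstitial progenitor list 5 of 21 members were lower and 1 higher, with 9 and 2 when adjusted over the list alone (median -0.21, camera adjusted p = 0.00797, and adjusted p = 0.196 with an estimated correlation). With a count minimum of 50 the camera call was lost (adjusted p = 0.0911), as with PBS replicate 3 and irisin replicate 1 both left out (0.0639). Dpp4, the enzyme used as a surface marker of those progenitors, did not pass (125 ± 22.4 to 135 ± 20.3 CPM, LFC 0.11 ± 0.14, adjusted p = 0.774). The falls were Smpd3, a sphingomyelinase (LFC -1.63 ± 0.19, adjusted p = 9.35e-05), Limch1 (LFC -1.02 ± 0.21, adjusted p = 0.00772), Ly6c1 (LFC -0.58 ± 0.13, adjusted p = 0.0188), Tek (LFC -0.59 ± 0.15, adjusted p = 0.0303) and, named after its value was seen, Has1 (LFC -1.03 ± 0.28, adjusted p = 0.0399). Sema3c, a semaphorin, was higher (LFC 0.70 ± 0.14, adjusted p = 0.00619). The falls numbered 1 without PBS replicate 1, 3 without PBS replicate 2, 2 without irisin replicate 2 and 3 without irisin replicate 3, and the rises 2, 3 and 0 without PBS replicate 1, PBS replicate 3 and irisin replicate 3. Limch1 was no longer called without PBS replicate 1 (adjusted p = 0.0526). Ly6c1 lost its call without PBS replicate 1 or irisin replicate 1 or 2 (adjusted p 0.0525 to 0.0874). The call of Tek was lost without PBS replicate 1 or 2 or irisin replicate 2 or 3 (adjusted p 0.0653 to 0.143). Has1 was no longer called without PBS replicate 1 or 2 or irisin replicate 2 or 3 (adjusted p 0.0979 to 0.154). Sema3c lost its call without irisin replicate 3 (adjusted p = 0.0503). Interstitial progenitor rises numbered 2 with DESeq2 or with limma-voom or with no low-count filter and 3 without both PBS replicate 3 and irisin replicate 1. The interstitial progenitor falls numbered 8 with total counts.

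Extracellular matrix genes were not called as a group. Of 37 tested 5 rose and 5 fell, with 7 and 5 when adjusted over the list alone (camera adjusted p = 0.897). P4ha2 and P4ha1, subunits of the enzyme that hydroxylates collagen prolines, rose from 345 ± 29.4 to 812 ± 17.8 CPM (LFC 1.24 ± 0.08, adjusted p = 1.06e-06) and from 645 ± 64.8 to 968 ± 26.8 CPM (LFC 0.59 ± 0.09, adjusted p = 0.000935). The other rises, Col1a1 (LFC 0.49 ± 0.11, adjusted p = 0.0155), Tnc (LFC 0.35 ± 0.09, adjusted p = 0.0359) and Lox (LFC 0.33 ± 0.09, adjusted p = 0.0391), and the falls of Lum, Col6a3 and Fbln2 were named after their values were seen. The falls were Eln, the gene of elastin (LFC -1.41 ± 0.25, adjusted p = 0.00333), Fbln1 (LFC -1.01 ± 0.11, adjusted p = 6.20e-05), Lum (LFC -0.76 ± 0.14, adjusted p = 0.00659), Col6a3 (LFC -0.56 ± 0.11, adjusted p = 0.00475) and Fbln2 (LFC -0.30 ± 0.08, adjusted p = 0.0405). The rises numbered 3 without PBS replicate 1 or 2 and 2 without irisin replicate 2 or 3, and the falls 9 without PBS replicate 3. The call of Col1a1 was lost without irisin replicate 2 or 3 (adjusted p 0.0725 to 0.0985). Tnc was no longer called without PBS replicate 1 or 2 or irisin replicate 2 or 3 (adjusted p 0.108 to 0.213). Lox lost its call without PBS replicate 1 or 2 or irisin replicate 1, 2 or 3 (adjusted p 0.111 to 0.185). The call of Fbln2 was lost without PBS replicate 1 or 2 or irisin replicate 1, 2 or 3 (adjusted p 0.119 to 0.218). Matrix rises numbered 3 with total counts, 8 with limma-voom, 9 with no low-count filter and 11 without both PBS replicate 3 and irisin replicate 1. The matrix falls numbered 13 without both PBS replicate 3 and irisin replicate 1.

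Among 24 matrix proteases and their inhibitors 4 rose and 7 fell, with 6 and 10 when adjusted over the list alone (camera adjusted p = 0.0916). Mmp11, the protease stromelysin-3, fell from 535 ± 63.9 to 144 ± 8.84 CPM (LFC -1.90 ± 0.10), Plau, which activates plasminogen, from 127 ± 34.3 to 49.2 ± 5.46 CPM (LFC -1.37 ± 0.19), and Timp3, an inhibitor of metalloproteases, from 76.2 ± 13.7 to 35.3 ± 0.0965 CPM (LFC -1.11 ± 0.13). Adamts9, a protease that cleaves proteoglycans, rose from 5.84 ± 1.10 to 23.9 ± 3.16 CPM (LFC 2.03 ± 0.20). The other rises, named after their values were seen, were Mmp9 (0.759 ± 0.795 to 5.47 ± 0.694 CPM, LFC 2.91 ± 0.57, adjusted p = 0.00238), Mmp8 (LFC 0.64 ± 0.15, adjusted p = 0.0234) and Timp1 (LFC 0.37 ± 0.08, adjusted p = 0.0111). The rises numbered 2 without PBS replicate 1 or irisin replicate 2, and camera called the list down without PBS replicate 3 (adjusted p = 0.0247). It also did so with total counts (0.0437), with no low-count filter (0.0289), with a count minimum of 50 (0.0303) and with PBS replicate 3 and irisin replicate 1 both left out (0.0239). Mmp8 was no longer called without PBS replicate 1 or 2 or irisin replicate 1 or 2 (adjusted p 0.0719 to 0.114). Timp1 lost its call without PBS replicate 1 or irisin replicate 2 or 3 (adjusted p 0.0528 to 0.0858).

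TGF-β response genes fell in 6 of 21 members and 1 rose, with 6 and 5 when adjusted over the list alone (camera adjusted p = 0.145, and 0.0437 without PBS replicate 3 and 0.0289 with no low-count filter). Tgfb3, a TGF-β ligand, fell from 92.3 ± 5.18 to 53 ± 4.75 CPM (LFC -0.80 ± 0.10), Ltbp1, a protein that binds latent TGF-β, from 766 ± 91 to 409 ± 35.9 CPM (LFC -0.90 ± 0.10), and Tgfbi, a matrix protein, from 43.9 ± 3.46 to 22 ± 3.93 CPM (adjusted p = 0.000647). Nox4, a hydrogen peroxide-producing oxidase, also fell (LFC -0.97 ± 0.18, adjusted p = 0.00423), and the member that rose, named after its value was seen, was Id2, an inhibitor of basic helix-loop-helix factors (LFC 0.61 ± 0.12, adjusted p = 0.00647). The rises numbered 2 without PBS replicate 3 or irisin replicate 1. Of 19 contractile genes of myofibroblasts, 1 fell, and 2 when adjusted over the list alone (median -0.15, camera adjusted p = 0.0262, and adjusted p = 0.442 with an estimated correlation). It was Des, the muscle filament desmin (LFC -1.13 ± 0.13, adjusted p = 7.90e-05), while Acta2, smooth muscle actin, did not pass (2157 ± 123 to 1796 ± 122 CPM, LFC -0.26 ± 0.09, adjusted p = 0.0976). Without PBS replicate 3 the falls numbered 3, and the camera call was lost without PBS replicate 1 (adjusted p = 0.0646), irisin replicate 1 (0.0682) and irisin replicate 3 (0.0805). TGF-β rises numbered 2 with limma-voom or with no robust dispersion and 3 with DESeq2 or with no low-count filter or without both PBS replicate 3 and irisin replicate 1. Contractile rises numbered 1 without both PBS replicate 3 and irisin replicate 1. The contractile falls numbered 2 with no low-count filter, 3 with total counts or with limma-voom and 6 without both PBS replicate 3 and irisin replicate 1.

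Glycolysis and hypoxia genes rose. Of 27 tested, 15 rose and none fell, with 18 and 1 when adjusted over the list alone (median log2 fold change 0.59, camera adjusted p = 8.93e-26). Slc16a3, the lactate transporter MCT4, rose from 32.6 ± 4.01 to 158 ± 12.6 CPM (LFC 2.27 ± 0.11, adjusted p = 7.28e-08), and Pdk1, a kinase that inhibits pyruvate dehydrogenase, from 16.7 ± 4.06 to 81.5 ± 5.30 CPM (LFC 2.27 ± 0.15, adjusted p = 8.86e-07). Pfkl, a phosphofructokinase, rose from 229 ± 5.24 to 535 ± 35.3 CPM (LFC 1.22 ± 0.08, adjusted p = 8.63e-07), and Pgk1, phosphoglycerate kinase, from 89.8 ± 1.07 to 184 ± 7.75 CPM (LFC 1.04 ± 0.08, adjusted p = 4.72e-06). Oxidative phosphorylation genes did not pass in any of 46 members, over all genes or adjusted over the list alone (camera adjusted p = 0.297). Of 15 fatty acid synthesis genes, 1 fell, and 2 when adjusted over the list alone (median -0.11, camera adjusted p = 0.0119, and adjusted p = 0.370 with an estimated correlation). That gene was Scd1, the desaturase that makes oleate (1590.0 ± 109 to 593 ± 29.1 CPM, LFC -1.42 ± 0.09, adjusted p = 3.52e-07), and the falls numbered 3 without PBS replicate 3. Fatty acid oxidation genes fell in 1 of 18 members, also 1 when adjusted over the list alone (camera adjusted p = 0.182, and 0.0289 with no low-count filter). That member was Etfb, an electron carrier of β-oxidation (LFC -0.46 ± 0.10, adjusted p = 0.0156), and without PBS replicate 3 there were 2 falls. The call of Etfb was lost without PBS replicate 1 or irisin replicate 2 or 3 (adjusted p 0.0594 to 0.0817). Of 6 thermogenic genes tested 2 rose, also 2 when adjusted over the list alone (camera adjusted p = 0.300). These were Dio2, the deiodinase that activates thyroid hormone (0.760 ± 0.338 to 2.83 ± 0.577 CPM, LFC 1.89 ± 0.47, adjusted p = 0.0186), and Tmem26, a beige fat marker (0.469 ± 0.550 to 2.59 ± 0.463 CPM, LFC 2.52 ± 0.68, adjusted p = 0.0206), both under 3 CPM. Dio2 was no longer called without PBS replicate 1 or irisin replicate 1 or 3 (adjusted p 0.0512 to 0.104). Tmem26 lost its call without PBS replicate 1 or 2 or irisin replicate 2 or 3 (adjusted p 0.0792 to 0.111). Without PBS replicate 3, 1 thermogenic gene was called lower. Glycolysis falls numbered 1 with total counts or without both PBS replicate 3 and irisin replicate 1. Fatty acid synthesis falls numbered 2 with total counts or with limma-voom and 6 without both PBS replicate 3 and irisin replicate 1. Fatty acid oxidation falls numbered 2 with limma-voom or without both PBS replicate 3 and irisin replicate 1. Thermogenic rises numbered 0 with a count minimum of 50 and 1 with DESeq2. The thermogenic falls numbered 1 with limma-voom or without both PBS replicate 3 and irisin replicate 1.

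Of 14 complement genes tested 6 rose and 2 fell, with 7 and 4 when adjusted over the list alone (median log2 fold change 0.40, camera adjusted p = 0.00365, and adjusted p = 0.125 with an estimated correlation). With limma-voom the camera call was lost (adjusted p = 0.0519). Cfb, factor B of the alternative pathway, rose from 23.8 ± 1.27 to 107 ± 12.2 CPM (LFC 2.16 ± 0.12, adjusted p = 1.39e-07), C1ra, a protease of the classical pathway, from 194 ± 8.57 to 337 ± 10.5 CPM (LFC 0.79 ± 0.08, adjusted p = 2.61e-05), and Serping1, the C1 inhibitor, from 2257 ± 277 to 4368 ± 357 CPM (LFC 0.95 ± 0.10, adjusted p = 5.66e-05). C7, a part of the membrane attack complex, fell (LFC -1.40 ± 0.14, adjusted p = 2.61e-05). Genes of antigen presentation on MHC class I rose in 9 of 16 members and fell in none, with 13 and 0 when adjusted over the list alone (median 0.68, camera adjusted p = 1.10e-09, and adjusted p = 0.251 with an estimated correlation). H2-K1, a class I heavy chain, rose from 398 ± 11 to 844 ± 161 CPM (LFC 1.09 ± 0.12, adjusted p = 6.77e-05), and H2-Q7, a related chain, rose too (LFC 1.76 ± 0.32, adjusted p = 0.00288). So did Psmb10, a subunit of the immunoproteasome (LFC 0.70 ± 0.12, adjusted p = 0.00263), and Tapbp, the peptide-loading chaperone tapasin (LFC 0.47 ± 0.09, adjusted p = 0.00426). With PBS replicate 3 and irisin replicate 1 both left out, H2-K1 was no longer called (adjusted p = 0.179). Complement falls numbered 4 with total counts.

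Interferon response genes varied between libraries of the same group. Of 38 tested 4 rose and none fell, with 5 and 0 when adjusted over the list alone (median log2 fold change 0.76, camera adjusted p = 3.04e-06, and adjusted p = 0.523 with an estimated correlation). The mean log2 CPM of the list was 3.58, 3.44 and 4.45 in PBS replicates 1, 2 and 3, and 4.50, 4.11 and 5.25 in irisin replicates 1, 2 and 3. In both groups it was lowest in replicate 2 and highest in replicate 3, and at each replicate number it was higher with irisin. The rises were Gbp2, a guanylate-binding protein (LFC 0.91 ± 0.13, adjusted p = 0.000580), Parp14, an ADP-ribosyltransferase (LFC 0.96 ± 0.15, adjusted p = 0.00106), Irf1, a transcription factor (LFC 0.59 ± 0.16, adjusted p = 0.0398), and Isg20, an exonuclease (LFC 0.54 ± 0.15, adjusted p = 0.0398). They numbered 12 without PBS replicate 3, and 2 without PBS replicate 1, PBS replicate 2 or irisin replicate 3. The call of Irf1 was lost without PBS replicate 1, 2 or 3 or irisin replicate 1 or 3 (adjusted p 0.0555 to 0.209). Isg20 was no longer called without PBS replicate 1 or 2 or irisin replicate 1, 2 or 3 (adjusted p 0.0817 to 0.179). Interferon rises numbered 2 with total counts, 7 with limma-voom, 11 without both PBS replicate 3 and irisin replicate 1 and 14 with no low-count filter. With the replicate number as a block they numbered 19 (camera adjusted p = 4.11e-23 at the preset correlation). The labels do not say that the numbers pair the libraries.

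Summed macrophage markers were 90.1 ± 6.89 CPM in PBS and 84.5 ± 12.7 CPM in irisin (exact permutation p = 0.6, adjusted p = 0.72 over 12 marker and quality lists). Most of this sum was Csf1r, named after its value was seen (59.7 ± 5.54 and 59.2 ± 5.16 CPM). Its exons share 873 bases with Hmgxb3 on the opposite strand, so the sum may say little about macrophages. Of 5 macrophage markers tested 1 fell, also 1 when adjusted over the list alone (camera adjusted p = 0.401), and it was Mertk, a receptor for apoptotic cells (LFC -1.42 ± 0.28, adjusted p = 0.00619). T, NK and innate lymphoid markers summed to 43.8 ± 9.05 and 21.1 ± 3.62 CPM (exact permutation p = 0.1, adjusted p = 0.40). Of the 2 tested Thy1, which stromal cells also express, fell (39.3 ± 9.57 to 16.1 ± 3.16 CPM, LFC -1.30 ± 0.20, adjusted p = 0.00138), also when adjusted over the list alone. Granulocyte and mast cell markers summed to 3.07 ± 0.677 and 8.90 ± 2.02 CPM (exact permutation p = 0.1, adjusted p = 0.40). The 1 marker tested, Camp, an antimicrobial peptide gene, rose from 0.523 ± 0.183 to 5.00 ± 1.66 CPM (LFC 3.19 ± 0.53, adjusted p = 0.000438), also when adjusted over the list alone. Ptprc, the pan-leukocyte gene of CD45, had at most 3 counts in a library. Endothelial markers summed to 540.2 ± 37.1 and 538 ± 16.7 CPM (exact permutation p = 1), and Tek fell among 5 tested, with 2 falls when adjusted over the list alone (camera adjusted p = 0.118). Tek lost its call without PBS replicate 1 or 2 or irisin replicate 2 or 3 (adjusted p 0.0653 to 0.143). Without PBS replicate 3 the endothelial falls numbered 2. Mesothelial markers did not pass in any of 5 members, nor when adjusted over the list alone (camera adjusted p = 0.827), and summed to 59.2 ± 5.71 and 63.2 ± 3.43 CPM (exact permutation p = 0.4). Macrophage marker falls numbered 0 with a count minimum of 50. Endothelial rises numbered 1 with no low-count filter. The endothelial falls numbered 2 with limma-voom or without both PBS replicate 3 and irisin replicate 1.

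Pericyte and smooth muscle markers summed to 2988 ± 156 and 3054 ± 137 CPM (exact permutation p = 0.6). Of 11 tested 2 rose (Ndufa4l2 and Steap4) and 3 fell, with 2 and 4 when adjusted over the list alone (camera adjusted p = 0.827). The falls were Des, Cspg4, the proteoglycan NG2 (LFC -1.63 ± 0.30, adjusted p = 0.00324), and, named after its value was seen, Abcc9, a channel subunit (LFC -0.98 ± 0.25, adjusted p = 0.0285). The call of Abcc9 was lost without PBS replicate 1 or 2 or irisin replicate 1, 2 or 3 (adjusted p 0.0580 to 0.152). Epithelial markers (3.23 ± 3.06 and 8.58 ± 8.29 CPM), erythroid markers (3.00 ± 0.833 and 3.01 ± 0.410 CPM) and B cell markers (1.06 ± 0.977 and 1.34 ± 0.666 CPM) had 1, 1 and 0 genes tested, none of which passed, also when adjusted over the list alone. As for RNA quality, none of 11 mitochondrially encoded genes passed, nor when adjusted over the list alone (camera adjusted p = 0.490), and they made up 0.846% to 0.916% of the counts of a library. Nuclear-retained RNAs passed in none of 6, with 2 lower when adjusted over the list alone (camera adjusted p = 0.706), and 1 was lower over all genes without PBS replicate 3. Ribosomal protein genes passed in none of 66, over all genes or adjusted over the list alone (median log2 fold change 0.13, camera adjusted p = 0.00836, and adjusted p = 0.657 with an estimated correlation). The ribosomal list's camera call was lost without PBS replicate 3 (adjusted p = 0.194), and also with PBS replicate 3 and irisin replicate 1 both left out (0.0639). Pericyte falls numbered 1 with a count minimum of 50 and 5 without both PBS replicate 3 and irisin replicate 1. Nuclear RNA falls numbered 1 with total counts or with limma-voom or with no low-count filter and 2 without both PBS replicate 3 and irisin replicate 1. Ribosomal protein rises numbered 1 with a count minimum of 50, 2 with limma-voom and 8 without both PBS replicate 3 and irisin replicate 1.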

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

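All alternatives were planned except leaving out PBS replicate 3 and irisin replicate 1 together and leaving out members shared between lists, which were chosen after the result was seen. Of the alternative values for the counts of calls, 42 stayed within 1.5 times the reported count and 15 moved further. For the counts of list members 1048 stayed so and 210 moved further. Of the list tests 612 stayed on their side of the threshold, 30 lost and 24 gained a call. Of these, 16 gained and 6 lost calls came with fry, which tests a list against no change and not against the other genes, and 15 lost calls with an estimated correlation. Of the values of named genes 3073 stayed, 242 lost and 53 gained a call. None of these reversed. The 912 calls ranged from 589 to 1290 without single libraries, the 516 higher genes from 336 to 705 and the 396 lower genes from 238 to 585. With PBS replicate 3 and irisin replicate 1 left out together, calls rose to 1680 (892 higher, 788 lower), and 5 immunomodulatory genes were lower in place of 3. That choice kept the closest pair of each group, which favours more calls. A test against a 1.5-fold change, which asks for larger effects by construction, called 273 (165 higher, 108 lower). Genes lower with irisin numbered 602 with total counts alone, where the median of all genes moved from -0.01 to -0.09, and 623 with limma-voom. For limma-voom and the left-out libraries the cause was not tested. The adipocyte differentiation list had camera adjusted p = 0.0501 with an estimated correlation, against 3.87e-41 with the preset one, and from 1.42e-46 to 3.40e-38 without single libraries. The shared calls were 908 of 912 with RLE factors, 909 with upper quartile factors, 818 with total counts, 785 with DESeq2 (835 called) and 908 with limma-voom (1327 called).

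Over all genes tested, there was no clear sign that the replicate numbers pair the libraries, but 3 libraries per group cannot exclude it. The interferon list had the same order of replicate numbers in both groups, which can also arise by chance with 3 libraries. Correlations of deviations from group means were -0.24, 0.16 and -0.18 for numbers 1, 2 and 3, and not every library correlated best with its own number (PBS replicate 3 with irisin replicate 1, 0.36). With the replicate block, 691 genes passed, 656 of them among the 912, and the interferon list had 19 rises in place of 4. At these depths the simulated data gave 44% recovery of 1.5-fold changes, so smaller changes are not excluded. Camera was not run with DESeq2 or without the robust estimate. Il1rl1, Fndc5 and Arc gave no value with a count minimum of 50, where they were not tested.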

Other observations

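The tests on splits of the libraries were planned, and the tests of scaling, cell types, microbial product, adipocyte share and cell cycle phase were chosen after the results were seen.

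Of 6 metallothionein and zinc genes tested 3 rose, also 3 when adjusted over the list alone with 1 lower there (median log2 fold change 0.89, camera adjusted p = 3.94e-10, and adjusted p = 0.0697 with an estimated correlation). They were Mt1 (120.2 ± 16.1 to 263 ± 20.7 CPM) and Mt2 (24 ± 5.72 to 79.4 ± 6.29 CPM), which bind zinc and copper, and Slc39a14, a zinc and iron importer (23 ± 2.71 to 98.4 ± 5.10 CPM, LFC 2.09 ± 0.12, adjusted p = 1.60e-07). The ferritin heavy chain Fth1 rose (2691 ± 154 to 4018 ± 223 CPM, LFC 0.58 ± 0.09, adjusted p = 0.000747) and the light chain Ftl1 fell (LFC -0.34 ± 0.08, adjusted p = 0.0161). Ftl1 lost its call without PBS replicate 1 or 2 or irisin replicate 2 or 3 (adjusted p 0.0626 to 0.120). Hmox1, which frees iron from haem, fell from 988 ± 264 to 422 ± 45.1 CPM (LFC -1.23 ± 0.19, adjusted p = 0.00656). Hmox1, Srxn1 (LFC -0.64 ± 0.12, adjusted p = 0.00446) and Ftl1 belong to the oxidative stress list of NRF2, of which 6 of 19 members fell and 1 rose (Fth1), with 7 and 1 when adjusted over the list alone (median -0.34, camera adjusted p = 0.00200, and adjusted p = 0.148 with an estimated correlation). The falls numbered 2, 3, 2 and 2 without PBS replicate 1, PBS replicate 2, irisin replicate 2 and irisin replicate 3. Metallothionein and zinc falls numbered 1 with limma-voom or without both PBS replicate 3 and irisin replicate 1.

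Epas1, the gene of the transcription factor HIF-2α, rose (327 ± 10.7 to 748 ± 67.2 CPM, LFC 1.19 ± 0.09, adjusted p = 1.87e-06), and so did Aldh1a2, from 258 ± 35.9 to 965 ± 32.5 CPM (LFC 1.90 ± 0.10, adjusted p = 1.28e-07), while Aldh1a3 fell from 1005 ± 118 to 382 ± 6.58 CPM (LFC -1.40 ± 0.09, adjusted p = 9.06e-07). All 3 genes, of which the last 2 encode enzymes that make retinoic acid, were named after their values were seen. Immediate-early genes fell in 8 of 25 members and rose in 3, with 11 and 3 when adjusted over the list alone (median -0.30, camera adjusted p = 0.00147, and adjusted p = 0.442 with an estimated correlation). Egr1 (LFC -1.13 ± 0.15, adjusted p = 0.000396), Egr2 (LFC -1.08 ± 0.18, adjusted p = 0.00191) and Spry4 (LFC -0.92 ± 0.18, adjusted p = 0.00660), which respond to growth factor signalling, were lower, and Junb (LFC 0.52 ± 0.09, adjusted p = 0.00271), Spry2 (LFC 0.45 ± 0.13, adjusted p = 0.0468) and Fosl2 (LFC 0.35 ± 0.10, adjusted p = 0.0466) higher, the last 2 named after their values were seen. The falls numbered 5 without PBS replicate 1, PBS replicate 2 or irisin replicate 3, and the rises 1 without PBS replicate 1, PBS replicate 2, irisin replicate 1 or irisin replicate 2. The call of Spry2 was lost without PBS replicate 1 or 2 or irisin replicate 1 or 2 (adjusted p 0.125 to 0.204). Fosl2 was no longer called without PBS replicate 1, 2 or 3 or irisin replicate 1, 2 or 3 (adjusted p 0.0546 to 0.189). Glucocorticoid targets had 3 rises and 1 fall among 15, with 4 and 1 when adjusted over the list alone (median 0.03, mean 0.52, camera adjusted p = 5.46e-05, and adjusted p = 0.164 with an estimated correlation). Without the 1 member shared with the acute-phase list, 2 of 14 rose and 1 fell (median 0.02, camera p = 0.0432, and p = 0.237 with an estimated correlation). With limma-voom the camera call was lost (adjusted p = 0.101). Lcn2, Mt2 and Angptl4, an inhibitor of lipoprotein lipase (LFC 1.23 ± 0.09, adjusted p = 1.17e-06), rose, and Tsc22d3, the glucocorticoid-induced leucine zipper, fell (LFC -0.65 ± 0.12, adjusted p = 0.00313). Immediate-early rises numbered 1 with total counts or with DESeq2 or with no robust dispersion. The immediate-early falls numbered 5 with a count minimum of 50. Glucocorticoid falls numbered 2 without both PBS replicate 3 and irisin replicate 1.

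Heat shock chaperones fell in 4 of 25 members and rose in 1, with 8 and 1 when adjusted over the list alone (median log2 fold change -0.12, camera adjusted p = 0.00797, and adjusted p = 0.370 with an estimated correlation). Hspa1a (LFC -1.13 ± 0.17, adjusted p = 0.000759) and Hspb1 (LFC -0.76 ± 0.11, adjusted p = 0.000685) were lower, as were Hsph1 (LFC -0.48 ± 0.13, adjusted p = 0.0342) and, named after its value was seen, Dnajb1 (LFC -0.37 ± 0.10, adjusted p = 0.0370), and the co-chaperone Stip1 was higher (LFC 0.35 ± 0.08, adjusted p = 0.0233). The falls numbered 2 without PBS replicate 2 or irisin replicate 2. Hsph1 lost its call without PBS replicate 2 or irisin replicate 1 or 2 (adjusted p 0.0950 to 0.184). The call of Dnajb1 was lost without PBS replicate 1 or 2 or irisin replicate 1, 2 or 3 (adjusted p 0.0636 to 0.197). Stip1 was no longer called without PBS replicate 1 or 2 or irisin replicate 1, 2 or 3 (adjusted p 0.0728 to 0.139). Of 19 Wnt signalling genes 1 rose and 2 fell, with 3 and 4 when adjusted over the list alone (camera adjusted p = 0.313). The Wnt-binding proteins Sfrp4 (LFC -1.27 ± 0.19, adjusted p = 0.000790) and Sfrp2 (LFC 0.43 ± 0.12, adjusted p = 0.0471) moved apart, and the transcription factor Tcf7l2 was lower (LFC -0.47 ± 0.10, adjusted p = 0.0110). Without PBS replicate 3 the Wnt list had 2 rises and 4 falls. Sfrp2 lost its call without PBS replicate 1, 2 or 3 or irisin replicate 2 or 3 (adjusted p 0.0550 to 0.236). The call of Tcf7l2 was lost without irisin replicate 2 or 3 (adjusted p 0.0760 to 0.0817). Of 20 p53 targets Fas, a death receptor, rose (LFC 1.21 ± 0.14, adjusted p = 9.99e-05), and Gdf15, a stress cytokine, and Phlda3 fell (LFC -1.12 ± 0.18, adjusted p = 0.00137 and LFC -0.74 ± 0.19, adjusted p = 0.0300), with 4 and 4 when adjusted over the list alone (camera adjusted p = 0.897). Phlda3 was no longer called without PBS replicate 1 or irisin replicate 1, 2 or 3 (adjusted p 0.0599 to 0.159). Without PBS replicate 3 there were 3 rises among the p53 targets. Of 26 genes of endoplasmic reticulum stress Trib3 rose (LFC 0.44 ± 0.12, adjusted p = 0.0470) and Atf3 fell (LFC -1.03 ± 0.21, adjusted p = 0.00758), with 1 and 1 when adjusted over the list alone (camera adjusted p = 0.827). Trib3 lost its call without PBS replicate 1, 2 or 3 or irisin replicate 1, 2 or 3 (adjusted p 0.0671 to 0.151). Of 25 cholesterol synthesis genes 1 rose and 1 fell, with 1 and 1 when adjusted over the list alone (camera adjusted p = 0.313). The rises of this list numbered 0 without PBS replicate 1, irisin replicate 1 or irisin replicate 2. The fall was that of Hsd17b7 (LFC -0.56 ± 0.11, adjusted p = 0.00738). The call of Hsd17b7 was lost without irisin replicate 2 or 3 (adjusted p 0.0564 to 0.0594). Heat shock rises numbered 0 with total counts. The heat shock falls numbered 7 with total counts or with no low-count filter, 8 with limma-voom and 9 without both PBS replicate 3 and irisin replicate 1. Wnt rises numbered 0 with total counts or with no robust dispersion or with a count minimum of 50 and 3 with limma-voom or without both PBS replicate 3 and irisin replicate 1. The Wnt falls numbered 4 with total counts or with limma-voom or with no low-count filter and 5 without both PBS replicate 3 and irisin replicate 1. The p53 rises numbered 2 with DESeq2 or with no low-count filter or with a count minimum of 50 or with mitochondrial and ribosomal protein genes left out and 3 with limma-voom or without both PBS replicate 3 and irisin replicate 1. The p53 falls numbered 4 without both PBS replicate 3 and irisin replicate 1. Endoplasmic reticulum stress rises numbered 0 with total counts or with DESeq2 or with no low-count filter. The endoplasmic reticulum stress falls numbered 4 without both PBS replicate 3 and irisin replicate 1. Cholesterol synthesis rises numbered 0 without both PBS replicate 3 and irisin replicate 1. The cholesterol synthesis falls numbered 2 without both PBS replicate 3 and irisin replicate 1.

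For the rise of the NF-κB and acute-phase lists, the choice among 5 scalings is argued against, since the lowest median of either list over them was 0.99. These scalings moved the median of all genes tested only between -0.01 and -0.09, so larger shifts were not tested. For leukocytes carried into the irisin wells, 65 immune markers summed to 138.0 ± 4.38 CPM in PBS and 116 ± 14.0 CPM in irisin, so no general gain was seen. That change is -0.163% of that of Saa3, Cxcl5, Ccl2 and Lcn2 (306 ± 6.87 to 13836 ± 743 CPM). Most of the immune sum was Csf1r and Thy1, and without Thy1 it went from 98.7 ± 7.48 to 99.8 ± 13.2 CPM (0.00811%). The granulocyte and mast cell markers, Camp among them, rose from 3.07 to 8.90 CPM (0.0431%). These percentages cannot decide, because the rise of the 4 genes is so large that any change of such low markers is a small part of it. A small gain of leukocytes, granulocytes among them, is therefore not excluded. A microbial product in the added protein could also raise the NF-κB and acute-phase genes. The interferon list, used as its sign, gave adjusted p = 0.523 with an estimated correlation, which does not decide. That fit had no replicate block, and the estimated correlation was 0.79, which lowers the chance of a call. With the replicate block 19 of the 38 members rose (camera adjusted p = 4.11e-23 at the preset correlation), but the estimated correlation was not run with that block. The preset correlation of 0.01 is far below 0.79, so that p does not decide either. A microbial product cannot be told apart from irisin/HSP90α here, because the labels name no protein added to the PBS wells.

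Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave 912 calls or more. In the highest of the others edgeR called 0 genes, DESeq2 up to 68 and limma-voom up to 81. There 113 to 979 genes had unadjusted p under 0.05, against 2236 in the real split. Each other split put PBS and irisin libraries on both sides, so the treatment difference added to the spread and kept calls low. These splits therefore do not show how many calls arise without an effect, and 10 are too few for a share under 0.05.

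The fall of the adipocyte lists also held under each of 5 scalings, where the highest median of either list was -1.30, which argues against the choice among them. Larger shifts than these scalings gave were not tested. Fewer differentiated adipocytes in the irisin wells would lower their markers by 1 common factor, and the 8 markers were spread unequally around a common log2 fold change of -2.10, from -2.90 for Aqp7 to -1.14 for Nnat, which did not pass (Cochran Q = 29.3, approximate chi-square p = 0.000128 from edgeR standard errors). This does not decide, since markers that other stromal cells also express would fall less. A smaller share of adipocytes and lower expression per cell therefore cannot be told apart here. Both are effects that irisin/HSP90α may have, and neither was tested directly.

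The cell cycle list passed the mixed test of fry (adjusted p = 5.86e-06), which takes changes in either direction. So did other lists that camera did not call, such as the extracellular matrix (7.38e-05), integrin (0.000139) and p53 (0.000566) lists. The oxidative phosphorylation list did not (0.434). Of 45 cell cycle genes 3 rose and 6 fell, with 3 and 9 when adjusted over the list alone (camera adjusted p = 0.792). The rises were Cenpa (LFC 0.44 ± 0.11, adjusted p = 0.0301), Ccnb2 and Plk1 of mitosis, and the falls Cdc6 (LFC -0.78 ± 0.18, adjusted p = 0.0187) and the helicase subunits Mcm2 to Mcm6 of replication (Mcm3 LFC -0.41 ± 0.10, adjusted p = 0.0269, Mcm6 LFC -0.47 ± 0.12, adjusted p = 0.0274), where Ccnb2, Plk1, Mcm2, Mcm4 and Mcm5 were named after their values were seen. Single calls were not stable, with no rise with total counts, 9 rises without both PBS replicate 3 and irisin replicate 1, and 3 falls with no robust dispersion, and with no rise without PBS replicate 1, irisin replicate 2 or irisin replicate 3, 1 without PBS replicate 2 and 7 without PBS replicate 3, and no fall without irisin replicate 1 or 2 and 1 without PBS replicate 2 or irisin replicate 3. The split by phase was prompted by these same calls, so it is a description and not a test, and it gave medians of 0.19 for 28 mitosis genes and -0.33 for 17 replication genes, a difference of 0.52, and 0.46 to 0.53 without single libraries. With fry the mitosis genes and the replication genes each had adjusted p = 0.0567 and did not pass, so whether cells shifted between phases is left open.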
